A study of Mus musculus with 9 samples.

How the data were processed

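Messenger RNA was measured in 9 libraries of ILC2s sorted from mouse pancreas, 4 from the PBS group and 5 from the IL-33 group. Per the labels' protocols, 5 to 15 ng of RNA entered a low-input library kit and libraries were sequenced as paired reads of 150 nt. The sample titles and the column names give 4 control libraries, which they call naive, and 5 IL-33 libraries. The series' design text gives 5 PBS and 4 IL-33 mice. The numbers of the sample labels were followed, and the libraries titled naive are called PBS here. Nothing in the labels says that each library came from a separate mouse, so p-values measure the spread between these libraries.

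The authors deposited a table of whole-number counts per Ensembl gene and a table of normalized signal. Per the submitters' processing notes, FastQC 0.11.9, Trimmomatic 0.39, STAR 2.7.7a, Picard, Salmon 1.6.0 and DESeq2 were used with the build GRCm38.p6. Their roles, the annotation, any filter and whether the deposited counts are rounded Salmon estimates are not given in the sources used here. The signal of the deposited normalized table equals the counts divided by 1 factor per library, as checked on the values. The kit is not stated to keep strand, so reads of overlapping genes and of near-identical copies (globins, amylases, trypsins, T cell receptor constant genes) could be shared between them.

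Of 20732 genes in the count table, 20571 (99.2%) matched a symbol. Gene coordinates and lengths were taken from GENCODE release M21, on GRCm38. Total counts lay between 14216976 and 21020023 per library. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. A gene at 0 in all libraries of a group was set at 3 counts per library, which is 0.133 to 0.286 CPM, and its change is given as a lower bound; list medians were the same with such genes at their bound. Ratios of genes with 1 to 3 counts in a group carry an exact binomial 95% interval.

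Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr with a minimum count of 10, robust quasi-likelihood fit and F-test, two-sided). Of the genes, 14405 passed the filter, and p-values were adjusted by the Benjamini-Hochberg method over them, with a threshold of 0.05. The biological coefficient of variation was 0.560. Values are TMM-scaled CPM, with mean ± SD over libraries, and log2 fold changes are IL-33 over PBS with their SE. Lists of genes, 41 in all (23 of cell functions, 17 of cell types and 1 of mitochondrially encoded transcripts), the comparison, the test and the rule for named genes were fixed before the data were examined. Camera (limma 3.58.1) tested the 35 lists with at least 3 measured genes at a preset correlation of 0.01, adjusted over those lists, and again with an estimated correlation. With the estimated correlation only the mitosis and the immediate early lists were called.

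The rule named the 10 largest rises and 10 largest falls among called genes with non-overlapping groups and a mean of at least 5 CPM, leaving out gene models, pseudogenes, receptor segments and histones. It added the 8 genes with the smallest adjusted p in the type 2 and ILC2 identity lists with Il5, Il13, Il4, Areg, Il1rl1, Klrg1 and Gata3, the 3 genes with the smallest adjusted p in each other list of functions and 2 in each list of cell types and of mitochondrially encoded transcripts, and the 3 most abundant genes of the acinar, endothelial, erythroid and T cell lists. Any other gene named was chosen after its values were seen.

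Shares of counts, total counts and genes detected were compared by an exact permutation test of the difference of means over all 126 splits (SciPy 1.17.1, two-sided), adjusted over 7 measures. Replicates of a group were checked for duplicates by a chi-square test, and all 16 pairs differed far beyond sampling noise (lowest chi-square per degree of freedom 52.6). The edgeR step was tested on data simulated with known changes from its own fitted dispersions. Among 13911 genes it recovered 18.4% of 98 genes changed 2-fold and 55.6% of 99 changed 4-fold, with 4 false calls.

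Alternatives planned beforehand were DESeq2 size factors (RLE) or library size alone in place of TMM, no filter or a filter of at least 5 CPM in at least 4 libraries, the replicate number as a block, removal of acinar and endocrine genes, limma voom with sample weights, the DESeq2 1.42.0 Wald test, limma-trend on log2 of the deposited signal plus 1, a threshold of 0.01, an estimated correlation and leaving out each library in turn. The acinar share as a covariate and removal of the trend with gene length and GC content were added after seeing the data. So were leaving Pcsk1 out of the endocrine share and leaving out the 3 IL-33 libraries high in beta-globin reads. The latter fit left out IL-33 replicates 1, 2 and 3 and kept replicates 4 and 5. In the fit with the replicate number as a block, number 5 occurs only in the IL-33 group. IL-33 replicate 5 therefore added nothing to the difference estimated with the block, and calls were harder to reach.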

Results

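RNA was sequenced from group 2 innate lymphoid cells (ILC2s), tissue-resident lymphocytes that lack antigen receptors and secrete type 2 cytokines, sorted from the pancreas of C57BL6/J mice. Mice had received PBS or IL-33, a cytokine of the IL-1 family that activates ILC2s through the receptor ST2, at 200 ng on days 0 and 1, and pancreata were taken on day 5. The sample labels give 4 libraries titled naive, called the PBS group here, and 5 in the IL-33 group. Cells were sorted as live CD45-positive cells negative for CD3, B220 and lineage markers and positive for KLRG1. Total counts per library lay between 14216976 and 21020023, and between 16015 and 17573 genes had at least 1 count. The series title places the cells in a study of ILC2s and a fibroblast progenitor niche, and the comparison asks how IL-33 altered the transcriptome of pancreatic ILC2s.

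Libraries differed in their content of RNA of acinar cells, the enzyme-secreting cells of the pancreas. Genes of the acinar list took 41.1% of the counts of PBS replicate 4 and 0.129% to 7.46% of those of the other PBS libraries, against 0.367% to 11.9% in the IL-33 libraries. The mean share was 12.7% ± 19.2 (SD, n = 4) with PBS and 6.40% ± 4.16 (SD, n = 5) with IL-33, a difference smaller than the spread between libraries (exact permutation test, two-sided, p = 0.746, adjusted p = 0.746 over 7 measures). Without PBS replicate 4 the difference turned to 3.215 percentage points higher with IL-33. The 50 most abundant genes took 60.7% of the counts of PBS replicate 4 and 17.3% to 26.2% in the other libraries. Genes of the erythroid list took 0.0222% ± 0.00855 (SD, n = 4) with PBS and 0.167% ± 0.134 (SD, n = 5) with IL-33, and genes of the endocrine list 0.00839% ± 0.00690 (SD, n = 4) and 0.0487% ± 0.00713 (SD, n = 5). Pcsk1 gave most of the endocrine share with IL-33. Without Pcsk1, a choice made after the data were seen, the endocrine share was 0.00444% ± 0.00829 (SD, n = 4) with PBS and 9.04e-04% ± 8.04e-04 (SD, n = 5) with IL-33 (exact permutation adjusted p = 0.762). With Pcsk1 counted, the groups did not overlap in either share, and the exact permutation p of 0.0159, the smallest that 4 against 5 libraries can give, became an adjusted p of 0.0556. Mitochondrially encoded transcripts took 1.45% ± 0.323 (SD, n = 4) and 1.31% ± 0.196 (SD, n = 5), with an exact permutation adjusted p of 0.685. Neither total counts (exact permutation adjusted p = 0.685) nor the number of genes detected (exact permutation adjusted p = 0.222) passed the threshold.

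**Figure D1:**
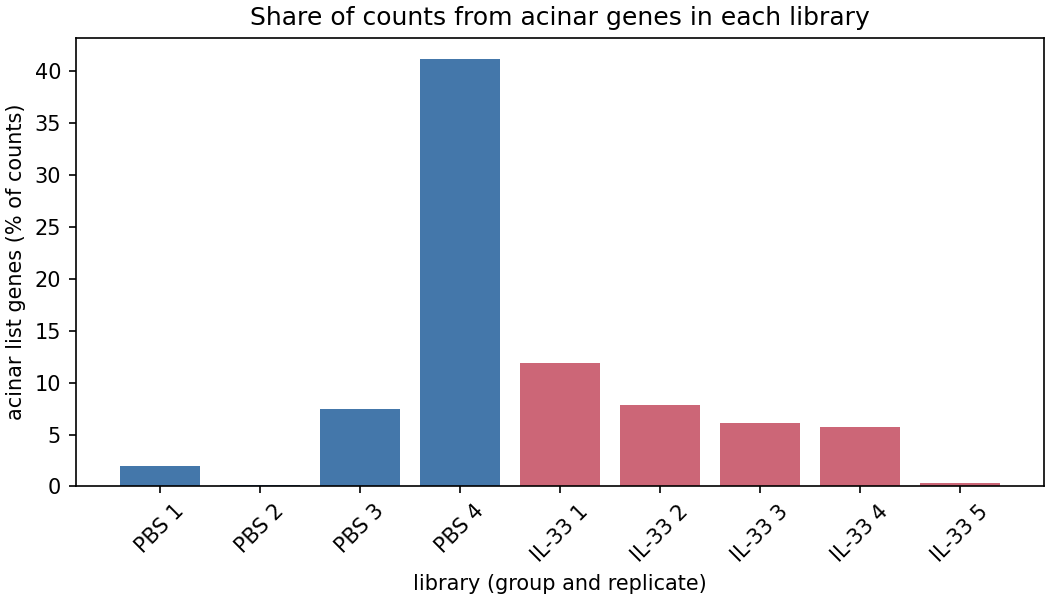
Bars give the percentage of each library's counts that fell on genes of the acinar list, for 4 PBS (blue) and 5 IL-33 (red) libraries. PBS replicate 4 stands at 41.1%, and the other libraries lie between 0.129% and 11.9%.

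On the first principal component, which held 44.3% of the variance of the 1000 most variable genes, the 4 PBS libraries lay on one side and the 5 IL-33 libraries on the other. The next component held 22.7%, with PBS replicate 4 at its lower end. Spearman correlations across genes, which are not independent replicates, were 0.946 to 0.960 between IL-33 libraries, 0.876 to 0.943 between PBS libraries and 0.832 to 0.899 between the groups.

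ILC2s from IL-33-treated mice carried more transcripts of Il13 and Il5 and of genes of mitosis, and fewer of immediate early genes, than ILC2s from PBS-treated mice. Of the lists of genes, mitosis and immediate early genes were called with a preset and with an estimated correlation (adjusted p = 0.0136 with an estimated correlation for each). Of 14405 genes tested with edgeR's quasi-likelihood test, 3633 (25.2%) had an adjusted p below 0.05, 1967 higher and 1666 lower with IL-33. At least 2-fold changes were found for 1107 higher and 1112 lower genes. Groups did not overlap at all for 3757 genes (26.1%), where chance gives 1.59%. The 4-against-5 split by treatment gave more changed genes than any of the other 99 among 100 splits drawn, of which the highest had 1111. With library size alone as the scaling the median of all genes moved up by 0.13 on the log2 scale. Then 1332 genes were higher and 644 lower, so that 67.4% of calls were higher in place of 54.1%. PBS replicate 4, with 41.1% acinar counts, had a TMM factor of 0.532, against 0.990 to 1.17 in the other libraries. Scaling by library size alone leaves out this factor. How much of the change in calls it accounts for was not tested. Leaving out the 3 IL-33 libraries high in beta-globin reads, a choice made after the data were seen, left 1396 changed genes. This fit set only IL-33 replicates 4 and 5 against PBS, so calls were harder to reach. It ended the call of 32 of the 109 named genes with one, among them Irf4, Irf9, Myb, Tcf7, Fabp4, Lck, Trbc1, H2-Ab1, Epcam, Fam84b, Ltbp4, Kdr, Col4a2, Hbb-bt and Hba-a1. Of these, the log2 changes of Ltbp4, Kdr and Fam84b grew in size and those of Epcam, Col4a2 and Hbb-bt shrank.

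The largest rises included those of Kif2c, Troap, Spdl1 and Kif4, which act in mitosis, and of Hbb-bt, a beta-globin (log2 change 9.74), which was not called with limma voom (adjusted p = 0.745). Kif2c, a kinesin that depolymerises microtubules at centromeres, had 0 counts in all PBS libraries and 28.3 ± 8.59 CPM (SD, n = 5) with IL-33, at least 147-fold higher against a floor of 3 counts per library (edgeR adjusted p = 9.0e-05). Troap and Spdl1, proteins of the mitotic spindle, were at 0 in PBS likewise and at least 53.4-fold and 52.8-fold higher, as were Pgam2, a phosphoglycerate mutase of muscle type, at least 60.8-fold, and BC030867, at least 56.9-fold. Il1r2, the decoy receptor of IL-1, rose by 10.50 on the log2 scale, from 0.101 ± 0.203 CPM (SD, n = 4) to 181 ± 90.7 CPM (SD, n = 5) (edgeR adjusted p = 6.0e-05), with all of its 8 PBS counts in PBS replicate 3, without which the PBS group is at 0 and the fitted log2 change was 14.70, a value that is no bound. For genes with 1 or 2 counts in the PBS group only a ratio with a 95% counting interval was taken, which covers counting error alone. Ttc39c, with 1 PBS count, had a ratio of 1097 (197 to 43346), and Kif4, a chromokinesin whose exons overlap those of an antisense gene, a ratio of 694 (192 to 5737). Paqr4, which also has an antisense overlap, had a ratio of 448 (124 to 3703). The PBS counts lay in PBS replicate 3 for Ttc39c and Paqr4 and in PBS replicate 1 for Kif4, without which the PBS group is at 0.

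The largest falls included genes known from matrix, endothelium and epithelium. AI593442 fell by 6.27 on the log2 scale (edgeR adjusted p = 0.0017). Ltbp4, a binding protein of latent TGF-beta, fell by 6.65 (edgeR adjusted p = 0.010), with 8 of its 9 IL-33 counts in IL-33 replicate 1. Its log2 change was -9.07 without that library and -5.61 without PBS replicate 4, and it was not called with limma voom (adjusted p = 0.0568) or the replicate number as a block (0.107). Mmp2, a gelatinase, fell from 67.0 ± 28.1 CPM (SD, n = 4) to 1.70 ± 0.993 CPM (SD, n = 5), a log2 change of -5.28 ± 0.73 (SE, edgeR adjusted p = 0.0010), and Bmp2, a bone morphogenetic protein, from 63.1 ± 14.1 to 1.92 ± 1.49 CPM (edgeR adjusted p = 5.1e-04). Cd9, a tetraspanin, had a log2 change of -5.36 and Ptprb, a phosphatase of endothelium, -5.75. Epcam, an epithelial adhesion molecule, fell by 4.43 and Fam84b by 4.38. The VEGF receptor gene Kdr, known from endothelium, fell by 6.01 (edgeR adjusted p = 0.018), a call lost without PBS replicate 4 (log2 change -4.62, adjusted p = 0.0617), and without IL-33 replicate 3 its log2 change was -9.11. Col4a2, a basement membrane collagen, fell by 4.30 (edgeR adjusted p = 0.045), and lost its call when any library except IL-33 replicate 5 was left out (adjusted p 0.0534 to 0.133), with a log2 change of -3.24 without PBS replicate 4 and -5.88 without IL-33 replicate 5. It was also not called with library size alone, no filter, the replicate block, the acinar covariate or the length trend removed (adjusted p 0.0587 to 0.0716). Log2 changes were -7.14 (AI593442), -7.52 (Ptprb) and -6.10 (Cd9) without IL-33 replicate 3, -5.20 (Epcam) without IL-33 replicate 4 and -5.03 (Fam84b) without IL-33 replicate 1.

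Il13 and Il5, which drive goblet cell and eosinophil responses, rose together. Il13 (chromosome 11, 53631324 to 53634702 on GRCm38) rose from 98.1 ± 35.3 CPM (SD, n = 4) to 1733 ± 559 CPM (SD, n = 5), a log2 change of 4.14 ± 0.37 (SE, edgeR adjusted p = 1.2e-04). Il5 (chromosome 11, 53720794 to 53725106) rose from 356 ± 23.9 to 1675 ± 429 CPM, a log2 change of 2.23 ± 0.20 (SE, edgeR adjusted p = 1.2e-04). Il6 rose by 2.27, Arg1, the arginase of ILC2s and alternatively activated macrophages, by 1.22 and Il4 by 1.19 on the log2 scale, and Csf2, Il3 and Retnla also rose. Arg1 and Il4 were not called with the replicate number as a block. Il10, an anti-inflammatory cytokine, had 1 count in the PBS group and a ratio of 557 (95% counting interval 99.8 to 22041), and Penk, the precursor of enkephalins, was at 0 in PBS and at least 31.3-fold higher, a call lost with limma voom. Lif fell from 373 ± 78.9 to 79.3 ± 20.7 CPM, Il2 fell from 43.1 ± 7.16 to 10.8 ± 2.81 CPM, and Tnf also fell. Areg, an epidermal growth factor receptor ligand, was at 756 ± 36.2 and 892 ± 313 CPM (edgeR adjusted p = 0.510), a difference not larger than the spread, and Calca, Ccl1, Furin and Il9 did not pass the test.

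Of 18 measured genes of this list, 10 rose and 3 fell over all genes tested, and 10 rose and 4 fell adjusted over the list alone. Camera placed the list higher than other genes (median log2 change 1.26, adjusted p = 0.0233), a call lost with an estimated correlation (adjusted p = 0.563 with an estimated correlation) and without PBS replicate 4 (adjusted p = 0.123). It was also lost with limma voom (adjusted p = 0.187) and with a filter of at least 5 CPM in at least 4 libraries (median 0.68, adjusted p = 0.285). That filter kept 14 genes of the list.

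Several surface receptors by which ILC2s are recognised fell, while Gata3 and Il1rl1 did not pass the test. Icos, a co-stimulatory receptor, fell from 613 ± 47.3 CPM (SD, n = 4) to 217 ± 61.2 CPM (SD, n = 5), a log2 change of -1.50 ± 0.20 (SE, edgeR adjusted p = 8.2e-04). Cd69, a retention and activation marker, fell by 1.59, Kit by 1.52, Il7r, the IL-7 receptor chain, by 1.28, Hes1 by 1.07 and Bcl11b by 0.85 on the log2 scale, and Il2ra also fell. Klrg1, the surface marker used in the sort, rose from 709 ± 81.9 to 1429 ± 200 CPM (log2 change 1.01, edgeR adjusted p = 7.9e-04), and Tcf7 rose by 0.70. Gata3, the lineage factor of ILC2s, was at 4518 ± 579 and 4030 ± 1586 CPM (edgeR adjusted p = 0.654), and Il1rl1, which encodes ST2, at 1181 ± 199 and 865 ± 157 CPM (edgeR adjusted p = 0.0723). Crlf2, Ets1, Gfi1, Id2, Il17rb, Il18r1, Il1rap, Il2rb, Maf, Rora and Thy1 did not pass the test either. Of 22 measured genes 2 rose and 7 fell, or 2 and 8 adjusted over the list alone, and camera did not call the list (median log2 change -0.26, adjusted p = 0.125). With library size alone as the scaling Bcl11b was no longer called, and 3 genes of the list rose and 5 fell. With the trend with gene length and GC content removed 4 rose and 6 fell, and without PBS replicate 4 the counts were 2 and 9.

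**Figure D2:**
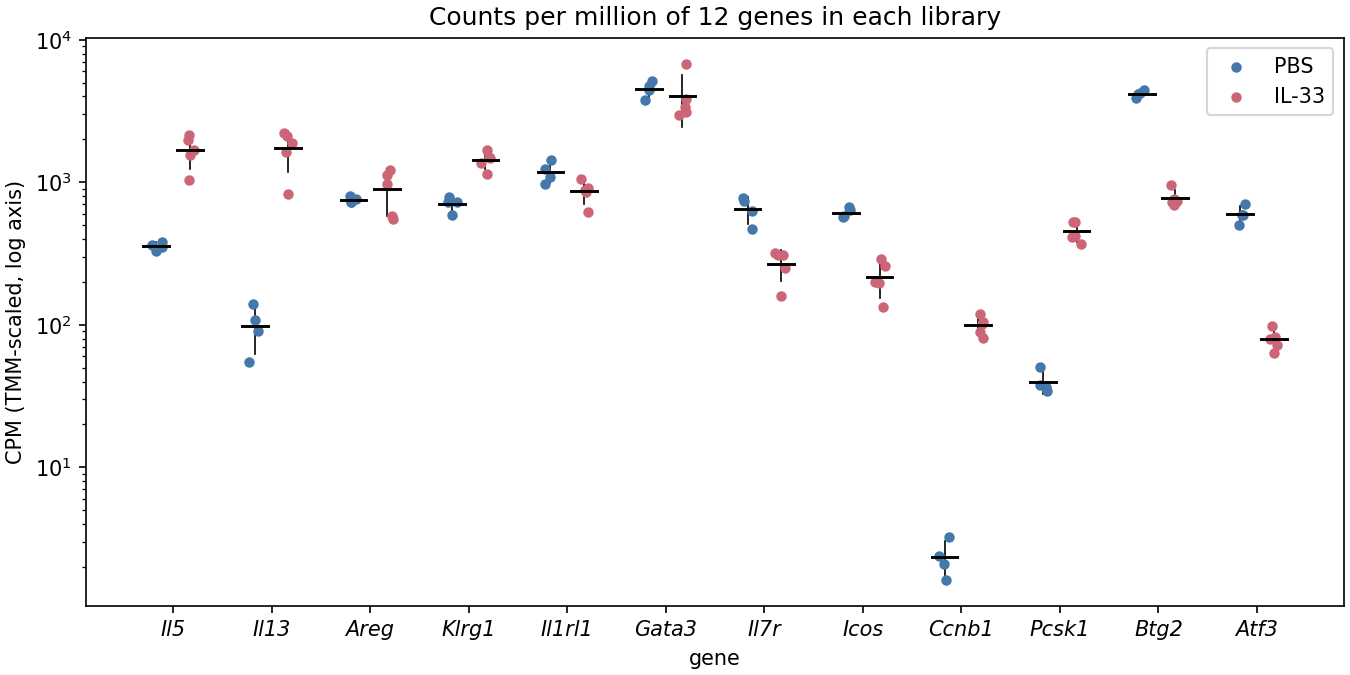
Points give CPM, on a log axis, of 12 genes in the 4 PBS (blue) and 5 IL-33 (red) libraries, with black bars for the mean and thin lines for 1 SD. Il13 stands at 98.1 CPM on average with PBS and 1733 CPM with IL-33, and Btg2 at 4190 and 777 CPM, while Gata3 and Areg overlap between the groups.

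Genes of the cell cycle rose together. Ccnb1, cyclin B, rose from 2.34 ± 0.683 CPM (SD, n = 4) to 99.03 ± 14.2 CPM (SD, n = 5), a log2 change of 5.40 ± 0.25 (SE, edgeR adjusted p = 6.8e-06). Birc5, or survivin, rose by 5.25 and Cenpa, a centromere histone, by 3.73 on the log2 scale. Of 26 genes of mitosis 25 rose over all genes tested and 25 adjusted over the list alone (median log2 change 4.35, camera adjusted p = 1.9e-32, adjusted p = 0.0136 with an estimated correlation). Among 26 genes of DNA replication Tyms rose by 2.88, Mcm5 by 2.49 and Tk1 by 3.61, and 22 rose over all genes tested, or 24 adjusted over the list alone. Their median log2 change was 2.29 (camera adjusted p = 9.4e-21, adjusted p = 0.119 with an estimated correlation). Without the 3 IL-33 libraries high in beta-globin reads 13 genes of mitosis and 14 of DNA replication rose, and with the replicate number as a block 15 and 18.

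In lists of glycolysis, oxidative phosphorylation and ribosomal proteins, some genes rose and others did not pass the test. Of 19 glycolytic genes 10 rose, or 12 adjusted over the list alone, and none was called lower except 1 without IL-33 replicate 3 (median log2 change 0.62, camera adjusted p = 8.8e-05, adjusted p = 0.140 with an estimated correlation). Gapdh rose by 1.93, Tpi1 by 1.53 and Pgk1 by 1.49 on the log2 scale. Of 29 nuclear genes of oxidative phosphorylation 20 rose, or 22 adjusted over the list alone (median log2 change 0.60, camera adjusted p = 1.2e-08, adjusted p = 0.140 with an estimated correlation), among them Cox5a by 1.73, Cox7a2 by 1.41 and Atp5c1 by 1.00. Of 30 ribosomal protein genes 16 rose, or 18 adjusted over the list alone (median log2 change 0.39, camera adjusted p = 0.0101, adjusted p = 0.630 with an estimated correlation), with Rps2 up by 1.15 and Rplp0 by 0.66. Short genes as a whole lay higher with IL-33. The median log2 change was 0.40 in the shortest of 5 equal groups of genes by length and -0.47 in the longest. With that trend removed, a choice made after the data were seen, the ribosomal list was no longer called (median 0.14, adjusted p = 0.448), with 9 genes higher and 4 lower. The list of oxidative phosphorylation then had 17 higher and 2 lower. With library size alone 8 glycolytic, 11 oxidative phosphorylation and 6 ribosomal genes were called higher. With the replicate number as a block 13 oxidative phosphorylation and 2 ribosomal genes were, and without the libraries high in beta-globin reads 10 and 3. With the filter of at least 5 CPM in at least 4 libraries the ribosomal list was not called (adjusted p = 0.0539). Plin2, a lipid droplet coat protein, rose by 2.07 and Pparg, not called with the replicate number as a block, by 1.08, while Fabp4 fell by 2.92. Fabp4 ran from 10.6 CPM in PBS replicate 2 to 60.3 CPM in PBS replicate 4, the library richest in acinar counts. Kdr ranked the PBS libraries in the same order. Whether the Fabp4 reads came from ILC2s was not tested. The list of lipid handling had 6 of 21 genes higher and 3 lower over all genes and adjusted over the list alone, and was not called (median 0.20, mean -0.0058, camera adjusted p = 0.461). Of 20 genes of cholesterol synthesis 3 rose and 2 fell (camera adjusted p = 0.643), and of 24 of the unfolded protein response and secretion 8 rose and 2 fell (camera adjusted p = 0.254), with the same counts adjusted over the list alone. Of the cholesterol genes 1 rose without PBS replicate 2 or 4 or IL-33 replicate 1, 2 or 4, 1 fell when any library except IL-33 replicate 1 was left out, and 0 were called with library size alone. Of the unfolded protein response genes 4 rose without PBS replicate 1 or IL-33 replicate 4 and 5 without PBS replicate 2, and 1 fell without PBS replicate 2 or 4 or IL-33 replicate 2, 3, 4 or 5.

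Immediate early genes fell. Btg2, an anti-proliferative gene of this class, fell from 4190 ± 225 CPM (SD, n = 4) to 777 ± 106 CPM (SD, n = 5), a log2 change of -2.43 ± 0.11 (SE, edgeR adjusted p = 6.8e-06). Klf4 fell by 3.30 and Atf3, a stress-responsive transcription factor, by 2.91 on the log2 scale. Of 25 genes of the immediate early and dissociation response 14 fell, or 16 adjusted over the list alone, and none was called higher (median log2 change -1.30, camera adjusted p = 4.4e-14, adjusted p = 0.0136 with an estimated correlation). With the DESeq2 Wald test 16 fell and 1 rose. Among 12 feedback regulators of cytokine signalling Spry2 fell by 2.43, Dusp5 by 1.54 and Socs2 by 1.25, and 5 fell in all, or 7 adjusted over the list alone (median -0.71, camera adjusted p = 0.0101, adjusted p = 0.140 with an estimated correlation). Of 20 interferon-stimulated genes 5 fell, or 6 adjusted over the list alone (median -0.71, camera adjusted p = 0.0318, adjusted p = 0.563 with an estimated correlation). That list was not called without PBS replicate 1 (adjusted p = 0.0863), PBS replicate 4 (0.0538) or IL-33 replicate 1 (0.0817), or with the filter of at least 5 CPM in at least 4 libraries (0.0539). With library size alone none of its genes was called, and 2 fell without PBS replicate 1 and 3 without IL-33 replicate 1, 2 or 4. Irf9 fell by 1.13.

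Ligands with receptors on fibroblasts moved in both directions. Il13, Il6 and Il4 rose, as given above, while Bmp2, Lif and Csf1, the macrophage growth factor (log2 change -2.71, edgeR adjusted p = 6.9e-04), fell together with Ltb (-2.36), Hbegf (-1.61) and Tnf. Of 21 measured ligands 3 rose and 6 fell, or 3 and 8 adjusted over the list alone, and the list was not called (median -0.61, camera adjusted p = 0.0701). Csf1, Ltb and Hbegf lie outside the rule for named genes and were chosen after their values were seen. In the list of receptors for neuropeptides and hormones Ramp3, a receptor activity-modifying protein, fell by 1.73 on the log2 scale. That list had 2 genes higher and 3 lower of 15, or 3 and 5 adjusted over the list alone (camera adjusted p = 0.0767). Cxcl3 rose by 2.97 and Ccl5 fell by 2.46, and Ccl24, an eosinophil attractant, was at 0 in PBS and at least 30.1-fold higher, a call lost with limma voom and with the replicate number as a block. Of 10 chemokines 2 rose and 2 fell, and the same number adjusted over the list alone (camera adjusted p = 0.615), with 1 higher without IL-33 replicate 1, 2, 4 or 5.

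Receptors and transcription factors of lymphocyte activation also moved in both directions. Pdcd1, which encodes PD-1, rose from 21.3 ± 9.77 CPM (SD, n = 4) to 276 ± 97.2 CPM (SD, n = 5), a log2 change of 3.70 ± 0.41 (SE, edgeR adjusted p = 3.1e-04), and Tnfrsf18, or GITR, fell by 1.03. In this list of co-stimulatory and inhibitory receptors 8 of 21 rose and 4 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.158). The falls were 2 without PBS replicate 1 or 2 or IL-33 replicate 2, 4 or 5, and 2 with library size alone. Batf rose by 1.55 and Irf4, its partner in T helper cells, by 4.21 (4.85 without PBS replicate 4), while Ikzf2 fell by 1.95. Myb was at 0 in PBS and at least 12.3-fold higher, a call lost with the replicate number as a block. Of 19 transcription factors linked to memory and exhaustion 7 rose and 4 fell, over all genes and adjusted over the list alone, with a median of -0.09, a mean of 0.43 with genes at 0 in PBS at their bound, and no call (camera adjusted p = 0.554). Among genes of trafficking S1pr4 rose by 2.16, Rgs1 by 2.09 and Itga4 by 1.16, and 6 of 18 rose and 4 fell, or 7 and 4 adjusted over the list alone (camera adjusted p = 0.0992). Of 7 cytotoxic granule genes 2 rose and 2 fell, or 2 and 4 adjusted over the list alone (median -0.34, mean 0.15 with Gzma, at 0 in PBS, at its bound, camera adjusted p = 0.596), and of 6 genes of inflammatory ILC2s and ILC3s 2 rose and 1 fell, or 2 and 2 adjusted over the list alone (median -0.57, mean 0.29, set test higher, camera adjusted p = 0.643). In the latter 0 fell without PBS replicate 2, 3 or 4 or IL-33 replicate 2, 3 or 5. Nfkbib rose by 1.25 and Nfkbiz and Birc3 fell by 1.48 and 1.26, and of 21 genes of the NF-kB list 6 rose and 3 fell, or 7 and 3 adjusted over the list alone (median -0.09, mean 0.31, camera adjusted p = 0.643). H2-Ab1, an MHC class II chain, rose by 2.50 (3.14 without PBS replicate 1), and 2 of 10 genes of that list rose, or 5 adjusted over the list alone (median 1.95, camera adjusted p = 0.0104, adjusted p = 0.265 with an estimated correlation), a call lost with the filter of at least 5 CPM in at least 4 libraries (adjusted p = 0.0539). The count of 2 was 4 without PBS replicate 3 and 1 without PBS replicate 2 or IL-33 replicate 2 or 4. Camera called 13 of 35 lists, 9 higher and 4 lower, and 2 with an estimated correlation. Without PBS replicate 4 the count was 8. Among 100 splits of the libraries, the real split included, 7 gave at least 13 lists.

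Markers of other cell types varied between libraries and in part with the groups. None of 28 acinar genes was called over all genes or adjusted over the list alone. Their median log2 change was -1.70 (camera adjusted p = 0.643), and it turned to 1.13 without PBS replicate 4. Of 10 endothelial genes 2 fell, or 5 adjusted over the list alone (median -2.61, camera adjusted p = 0.0239, adjusted p = 0.563 with an estimated correlation), and the list lost its call without PBS replicate 3 (adjusted p = 0.0523) or PBS replicate 4 (0.117) and with the filter of at least 5 CPM in at least 4 libraries (0.261). The number of its genes that fell was 4 without PBS replicate 2 and 1 without PBS replicate 3 or 4 or IL-33 replicate 2. All 4 erythroid genes rose over all genes and adjusted over the list alone (median 5.97, camera adjusted p = 0.0357, adjusted p = 0.563 with an estimated correlation). Hba-a1, an alpha-globin, rose from 127 ± 40.4 to 587 ± 393 CPM, while Hbb-bt, a beta-globin, was at 149 to 515 CPM in IL-33 replicates 1, 2 and 3, at 2.38 and 0.799 CPM in replicates 4 and 5 and at most 0.456 CPM with PBS. Globin genes share reads with near-identical copies. The median of the erythroid list lay between 9.14 and 9.30 when any PBS library was left out. In those fits 5 of its genes passed the filter in place of 4, so the medians are not of the same genes. The list was not called without PBS replicate 4 (adjusted p = 0.0594), IL-33 replicate 1 (0.0659) or IL-33 replicate 3 (0.0548). It was also not called with limma voom (adjusted p = 0.289), the acinar share as a covariate (0.0590) or the length trend removed (0.0882). Nor was it called without the 3 IL-33 libraries high in beta-globin reads (median 1.29, adjusted p = 0.0824). Hbb-bt had a log2 change of 10.50 without PBS replicate 3 and 9.001 without IL-33 replicate 3. Pcsk1, a prohormone convertase, rose by 3.50 on the log2 scale from 39.8 ± 7.18 CPM (SD, n = 4) to 452 ± 72.6 CPM (SD, n = 5) (edgeR adjusted p = 7.1e-06) and was the only gene called, of 4 measured, in the endocrine list. Ins2, insulin, was at 233 CPM in PBS replicate 4 and at most 2.65 CPM elsewhere. The endocrine list had a median of 0.10, a mean of -0.51 and a camera call for higher (adjusted p = 0.0239, adjusted p = 0.147 with an estimated correlation), which was lost on leaving out any of the PBS libraries (adjusted p 0.0538 to 0.101). Its median lay between -1.24 without IL-33 replicate 1 and 0.96 without PBS replicate 4. In the first of these fits 3 genes of the list passed the filter and in the other 6, in place of 4. These medians are therefore not of the same genes. The call was also lost with library size alone (adjusted p = 0.151), no filter (0.138), limma voom (0.296) and without the libraries high in beta-globin reads (0.152). Of 8 T cell genes, Lck fell by 0.95 and Trbc1 by 0.55, and the list was not called (median 0.07, mean 0.41, set test lower, camera adjusted p = 0.797). Neither gene was called with library size alone, and Trbc1 was not called with the replicate number as a block. The lists of ductal cells (1 of 6 lower, adjusted p = 0.643), fibroblasts (1 of 6 lower, adjusted p = 0.668), macrophages (0 of 8, adjusted p = 0.987), mast cells and basophils (1 higher and 1 lower of 4, adjusted p = 0.797) and mitochondrially encoded genes (2 of 13 lower, adjusted p = 0.183) were not called by camera, with the same counts adjusted over the list alone. Nor were those of regulatory T cells (1 higher and 2 lower of 4, median 0.24, mean 0.35, set test lower, adjusted p = 0.643) and of NK cells and ILC1s (1 higher and 2 lower of 3, median -2.46, mean -0.28 with Gzma at its bound, set test lower, adjusted p = 0.267), with the same counts adjusted over the list alone. Too few genes were measured to test the lists of dendritic cells (1 of 2 higher), B and plasma cells (1 higher and 1 lower of 2), ILC3s (0 of 1), eosinophils (0 of 1, or 1 higher adjusted over the list alone), adipocytes (1 of 2 lower) and neutrophils (0 measured). Several of these small counts rest on single libraries. The count of lower genes was 0 for fibroblasts without PBS replicate 3, 1 for regulatory T cells without PBS replicate 1 or 2 or IL-33 replicate 1, 2 or 3, and for mitochondrially encoded genes 4 without PBS replicate 2 and 1 without PBS replicate 3 or 4 or IL-33 replicate 2, 3 or 5. The count of higher genes was 2 for mast cells and basophils without PBS replicate 3, 0 for dendritic cells without IL-33 replicate 4, and 1 for eosinophils without PBS replicate 2. Counts of 0 became 1 without PBS replicate 1 (higher, macrophages and T cells), PBS replicate 2 (lower, macrophages), PBS replicate 3 (lower, endocrine cells) and PBS replicate 4 (higher, ductal cells, fibroblasts and mitochondrially encoded genes).

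**Figure D3:**
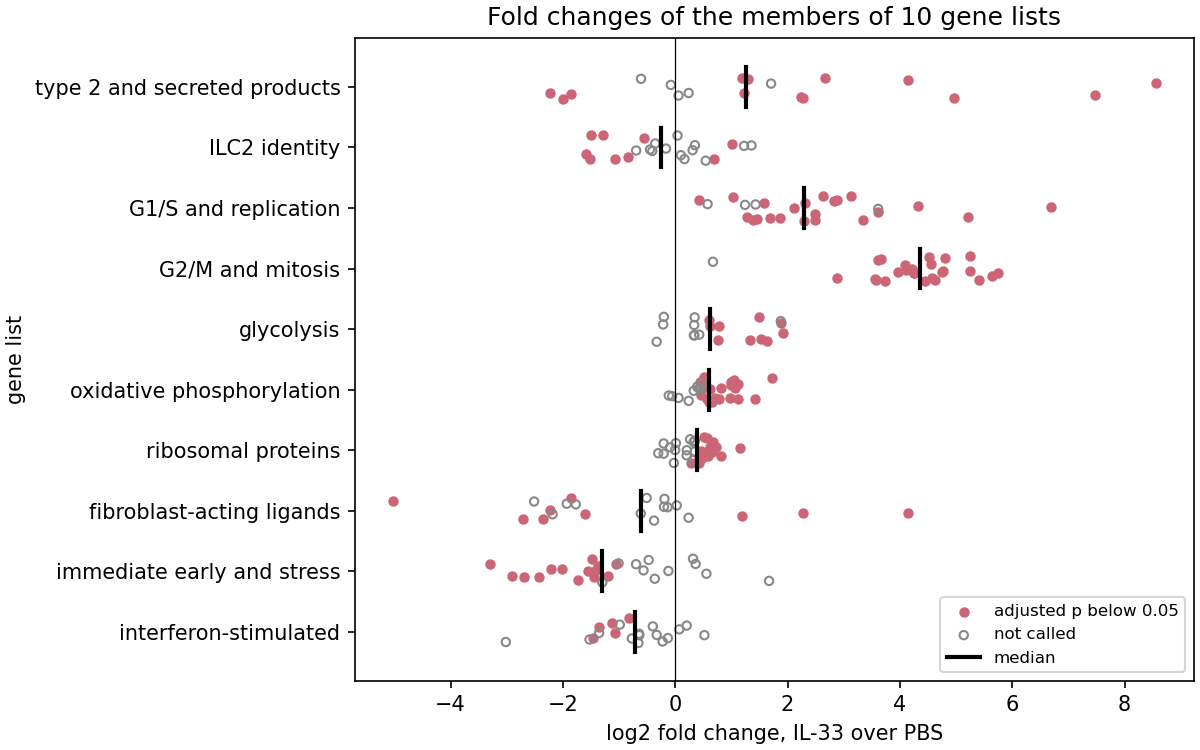
Points give the log2 fold change, IL-33 over PBS, of each measured gene in 10 lists, filled where the adjusted p was below 0.05, with a bar for the median. Genes at 0 in all PBS libraries are drawn at the lower bound of their change. The median of the mitosis list is 4.35 and that of the immediate early list -1.30.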

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

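The tests of both patterns weighed here and of the other splits of the libraries were chosen after the results they measure had been seen. In 267 groups of values, 38 held a library far from the others of its group, with a gap to the nearest library that took most of the group's range. For independent, normally spread values the rule flags about 1 in 20 groups, or 13.35 of 267. The groups here are not all of that kind, so the 2 numbers cannot be compared as a test. A gene with counts in 1 PBS library only has a gap of 1 in any case, and pancreatic genes rose together in PBS replicate 4.

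PBS replicate 4 stood apart in 11 measures. The gap as a share of the range was 0.917 for the counts in the top 50 genes, 0.907 for the endocrine share, 0.997 for Ins2, 0.878 for Ctrc, 0.925 for Cela1, 0.908 for Cela2a, 0.895 for Amy2a2, 0.928 for Ctrb1, 0.909 for Sox9 and 0.902 for Apoe, all high, and 0.930 for Nkg7, which was low. Other PBS libraries stood apart as follows. PBS replicate 1 was high for Kif4 (1) and Gbp2 (0.854) and low for Mcm5 (0.955). PBS replicate 2 was high for Il10 (1), Il4 (0.941) and Cxcl3 (0.840) and low for Ptprb (0.928) and Sec61b (0.877). PBS replicate 3 was high for Il1r2 (1), Ttc39c (1), Paqr4 (1), Nfkbib (0.966) and H2-Oa (0.838) and low for Herpud1 (0.918).

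Among the IL-33 libraries, replicate 3 was high for Kdr (0.921), Ptprb (0.830), Gata3 (0.771), Btg2 (0.739), Ighm (0.871) and Cpa3 (0.752) and low for Paqr4 (0.737). Replicate 2 was high for Spdl1 (0.788) and low for the mitochondrial share (0.825) and Mmp2 (0.717). Replicate 1 was high for Ltbp4 (0.895), replicate 4 low for Bcl11b (0.756) and replicate 5 high for Rpl3 (0.739).

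The real split ranked first in the number of changed genes: 1 of 100 splits of the 9 libraries, the real one, gave 3633 genes, and the highest other gave 1111. The same held for genes changed at least 2-fold (1 of 100, 2219 against 746) and for those adjusted over the list alone (1 of 100, 249 against 165). With 100 splits drawn, 1 of 100 is the smallest share possible. Every other split mixes PBS and IL-33 libraries in at least 1 group. These ranks cannot tell treatment from another difference aligned with the groups. Chance cannot be excluded for the number of lists called by camera, where 7 of 100 splits gave at least 13 and the highest other gave 14.

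Short genes lay higher and long genes lower with IL-33, with a Spearman correlation of -0.30 across 14327 genes, which are not independent. Calls followed length too. In the shortest of 5 equal groups of genes 21.4% were called higher and 3.66% lower, against 5.24% and 23.9% in the longest. With the trend removed the ribosomal protein list lost its call and its median fell from 0.39 to 0.14, so the trend may account for that rise. The oxidative phosphorylation list was still called with a median of 0.56, which argues against the trend as its whole cause. Slopes on log2 length were taken of log2 CPM relative to each gene's mean over the 9 libraries, so only differences between libraries carry meaning. They were lower in all IL-33 than in all PBS libraries (difference of means -0.178, exact permutation p = 0.0159). Recovery of long transcripts that differed between the groups cannot be told apart from an effect of IL-33 on short genes, because no batch or RNA quality is given in the labels.

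Immediate early genes fell with IL-33, and acinar RNA as the whole cause is argued against by a list median of -1.17 with the acinar share as a covariate. Gene length is argued against by a median of -1.30 with the length and GC trend removed. Induction during tissue dissociation that differed between groups remains open. The 6 heat-shock genes of the list, which lay on both sides of 0, had a median of 0.10 against -1.44 for the other 19, and no handling batch is given in the labels. An effect of IL-33 itself is likewise untested apart from the group difference.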

How the results depend on the processing

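The acinar covariate, the removal of the length and GC trend and the endocrine share without Pcsk1 were chosen after seeing the data. So was the fit without the 3 IL-33 libraries high in beta-globin reads, called the beta-globin libraries below. That fit kept only IL-33 replicates 4 and 5 beside the PBS libraries. The other alternatives were planned. No gene called in both fits changed direction under any alternative, except 1 with the length trend removed. With that trend removed 1761 genes were called higher, 1434 of them among the 1967 higher genes of the main fit. Of 1414 genes then called lower, 1121 were among the 1666 lower genes of the main fit. Of 109 named genes with a call, 68 kept it under every alternative fit that tested them, and none of the 109 reversed in such a fit. A gene that an alternative filter left out was not counted as lost, and the threshold of 0.01 was not applied to this count. A stricter threshold lowers the number of calls by construction, and with fewer libraries a call is harder to reach at the same spread. For the other changes below the cause was not tested. With library size alone 1976 genes changed, 644 of them lower (623 at least 2-fold lower). DESeq2 called 2588 lower, 1698 of them at least 2-fold. In simulated data it made 57 false calls among 163. Those data were drawn from dispersions fitted by edgeR, and DESeq2 ran on 14405 genes against 13911 for edgeR. The simulation thus favours edgeR and does not show that the additional DESeq2 calls are false. At an adjusted p below 0.01, 1786 genes changed (1019 higher, 767 lower). Without the 3 beta-globin libraries 1396 changed (732 higher, 664 lower), 1171 at least 2-fold (565 higher, 606 lower). The stricter count filter left 6 lists (4 higher, 2 lower) and the estimated correlation 2 lists (1 higher, 1 lower). Leaving out a library gave 8 to 14 lists, 2 to 6 of them lower, and 2676 to 3695 genes. Without the beta-globin libraries higher genes numbered 4 (co-stimulatory and inhibitory receptors), 3 (lipid handling), 3 (unfolded protein response), 3 (trafficking), 3 (memory and exhaustion factors), 14 (DNA replication), 13 (mitosis), 10 (oxidative phosphorylation) and 3 (ribosomal proteins). They numbered 1 in ILC2 identity, inflammatory ILC2s and ILC3s and cytotoxic granules, and 0 in cholesterol synthesis, MHC class II and the dendritic, B and plasma, regulatory T, NK and ILC1, mast and basophil and erythroid lists. Lower genes numbered 3 in cytokine feedback and 1 in trafficking, the unfolded protein response, chemokines, regulatory T cells and mitochondrial transcripts. They numbered 0 in lipid handling, cholesterol synthesis, interferon, inflammatory ILC2s and ILC3s and the ductal, fibroblast, endothelial, T cell and adipocyte lists. Higher genes numbered, with library size alone, 11 in oxidative phosphorylation, 6 in ribosomal proteins, 0 in cholesterol synthesis and in dendritic cells and 1 in fibroblasts. Lower genes then numbered 2 in co-stimulatory and inhibitory receptors and in trafficking, 3 in cytokine feedback and 1 in the unfolded protein response, chemokines, regulatory T cells and mitochondrial transcripts. They numbered 0 in cholesterol synthesis, interferon, T cells and inflammatory ILC2s and ILC3s.

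Replicate numbers 1 to 4 are shared by both groups but showed no pairing of the libraries. Deviations of same-numbered libraries correlated at -0.0564 to 0.0670, and 0 of 4 correlated best with their own number. Number 5 occurs only in the IL-33 group, so with the block IL-33 replicate 5 added nothing to the estimated difference. The block also fits more coefficients to the same libraries, so calls were harder to reach. How many of the lost calls this accounts for was not tested. With the replicate block 1457 genes changed (791 higher, 666 lower), 1195 at least 2-fold (604 higher, 591 lower), with 6 higher genes in the type 2 list, 5 in co-stimulatory and inhibitory receptors, 3 in NF-kB, 2 in lipid handling, 3 in the unfolded protein response, 4 in memory and exhaustion factors, 1 each in cholesterol synthesis, chemokines and neuropeptide and hormone receptors and 0 in cytotoxic granules, dendritic cells, regulatory T cells and NK cells and ILC1s. Higher genes then numbered 15 in mitosis, 13 in oxidative phosphorylation, 2 in ribosomal proteins and 1 in fibroblasts. Lower genes then numbered 2 in interferon, 2 in co-stimulatory and inhibitory receptors, 1 each in trafficking, cholesterol synthesis, T cells, regulatory T cells and mitochondrial transcripts, and 0 in the unfolded protein response and in inflammatory ILC2s and ILC3s. The block ended 20 of 109 named calls, and turned log2 changes to 0.89 (Cela1), 0.99 (Cela2a), 1.12 (Amy2a2), 1.61 (Ctrb1), 0.11 (Ins2) and 0.16 (Sox9) and list medians to 1.32 (acinar) and 1.72 (ductal).

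The median of the called endocrine list turned, while its set test kept its direction, to -0.87 with no filter, -0.47 with the length trend removed and -0.35 without the beta-globin libraries, and ranged from -1.24 to 0.96 on leaving out a library. Without Pcsk1 the difference in endocrine share turned to -0.00354 percentage points. The other reversals were of results without a call. With limma voom they were 0.16 (Ctrc), 0.70 (Cela1), 0.74 (Cela2a), 0.72 (Amy2a2), 1.79 (Ctrb1), and list medians of 1.21 (acinar) and 1.70 (ductal). With limma-trend they were 0.0926 (Amy2a2) and 0.87 (Ctrb1), with the acinar covariate 0.37 (Ctrb1), with the length trend removed -0.0543 (Areg), and for Trbc2 0.13 with library size alone and 0.0308 without the beta-globin libraries. The set test of the macrophage list turned at medians of 0.62 (library size alone), 0.79 (voom), 1.16 (acinar covariate) and 0.11 (length trend removed), and that of the T cell list at 0.19 (library size alone). Leaving out a library gave ranges of -2.85 to 0.71 (Cela1), -2.57 to 0.70 (Cela2a), -2.07 to 0.89 (Amy2a2), -2.12 to 1.598 (Ctrb1), -6.45 to 0.90 (Ins2) and -0.0554 to 0.0682 (Trbc2), and list medians of -2.11 to 1.13 (acinar), -2.93 to 1.93 (ductal), -1.48 to 0.0417 (fibroblast) and -0.0583 to 2.20 (macrophage). The difference in acinar share ranged from -10.5 to 3.215 percentage points and that of the 50 top genes from -13.0 to 0.892, the higher end in each without PBS replicate 4.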

Other observations

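All tests in this part were chosen after the results were seen, and the gene families below were picked by symbol from the table of all genes. T cell receptor gamma constant genes fell with IL-33. Tcrg-C1 (chromosome 13, 19214103 to 19217024 on GRCm38) fell from 484 ± 106 CPM (SD, n = 4) to 13.4 ± 4.53 CPM (SD, n = 5), a log2 change of -5.17 ± 0.29 (SE, edgeR adjusted p = 1.2e-05). Tcrg-C3 fell by 5.07, Tcrg-C2 by 4.05 and Tcrg-C4 by 0.79. With library size alone 3 of these 4 genes were called lower. Tmem176b and Tmem176a, membrane proteins of lymphoid and myeloid cells, fell by 3.28 and 2.87 on the log2 scale. Of 9 genes with Gimap symbols, GTPases of lymphocyte survival except for Gimap1os, a non-coding transcript that also fell, 6 fell, or 4 with library size alone (camera adjusted p = 4.6e-06 over 16 families, adjusted p = 0.0821 with an estimated correlation), among them Gimap3, from 643 ± 113 to 108 ± 29.5 CPM. Gvin1, an interferon-inducible GTPase, fell by 3.72, and 6 of 15 guanylate-binding and related GTPases fell, or 3 with library size alone (adjusted p = 0.169 with an estimated correlation).

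Histone cluster genes rose, 42 of 56 with a median log2 change of 2.49 (adjusted p = 0.0606 with an estimated correlation), and 36 of 56 with the length trend removed. Of 38 proteasome subunits 20 rose (adjusted p = 0.0663 with an estimated correlation), with library size alone 11 rose, with RLE scaling 20 rose and 2 fell, and with the length trend removed 21 rose and 1 fell. Of 76 mitochondrial ribosomal proteins 32 rose and 1 fell (adjusted p = 0.0806 with an estimated correlation), against 18 and 0 with library size alone and 21 and 3 with the length trend removed. Kinesins, motors of the spindle among other roles, had 10 of 26 higher and 1 lower (adjusted p = 0.0175 with an estimated correlation), and 12 higher and 0 lower with the length trend removed.

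The fall of the gamma constant genes was weighed against T cells among the sorted cells, which the CD3 gate would remove. Cd3d, Cd3e and Trdc stood at 0.432, 2.59 and 3.90 CPM with PBS, far below Tcrg-C1, and Cd3g, at 255 and 281 CPM, did not follow its fall. The median log2 change of the 4 T cell genes was 0.59, and none of the 4 was called. Trdc had a log2 change of -0.72 (edgeR adjusted p = 0.289). Cd3d and Cd3e were low, with wide errors (SE 1.32 and 1.08), so the median cannot decide whether T cells were lost. Reads moved from copy to copy would leave the sum in place, and the summed CPM of the 4 copies fell by 2.01 on the log2 scale, from 999 ± 198 (SD, n = 4) to 249 ± 29.3 (SD, n = 5) (exact permutation p = 0.0159, the smallest these groups can give). Whether the level fell within ILC2s or other ILC2s were present after IL-33 was not tested.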
